A study of Mus musculus with 12 samples.

How the data were processed

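The series holds 12 Affymetrix arrays of liver RNA from 129Sv mice aged 12 weeks, per the labels. Wild-type mice and mice lacking SIRT3, a deacetylase of the mitochondrion, were fed a standard diet or were weaned onto a high-fat Western diet with 42% fat, and all were fasted for 24 h before killing. The 4 groups of genotype and diet hold 3 arrays each, and groups and replicate numbers were taken from the labels.

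The deposited values are log2 expression values, 1 column per array, made by the authors with RMA in Affymetrix Expression Console, per the labels; the version and the options are not stated. RMA corrects background, normalizes the arrays of 1 run to a common distribution and summarizes the probes of each probe set. A check of the deposited values points to separate runs for the diets. Of the probe sets, 335 lack a value on all standard-diet arrays and have one on all high-fat arrays. Pairs of arrays of different diets share a median of 193 identical values (176 to 227). Within the standard diet the median is 289 (261 to 317), and within the high-fat diet 237 (204 to 255), where the range overlaps. Separate runs are taken as given below, and another difference in handling that follows the diets would not be told apart from them. The comparisons of genotype and their difference between the diets therefore lie within runs, while each comparison of diets lies across runs. No further normalization was applied. The array medians lay between 6.34 and 6.47 on the log2 scale. The number of arrays limits the precision, and the depth of a sample has no counterpart here.

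Of 35557 probe sets, 21789 were paired with 1 gene symbol, 1621 with several symbols, and 12147 were not listed in the gene table used. The Entrez ID of 21698 single-gene probe sets matched the RefSeq gene table. For each of the 999 genes with more than 1 probe set, the set with the highest mean over the 12 arrays was kept, which left 19938 genes. A number of well-known liver genes are not listed in that table and were not analysed here. One value, for Akr1d1 on high-fat knockout replicate 2, was missing.

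A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along an intensity trend (8 residual and a median of 14.5 total degrees of freedom). Genotype was compared within each diet and averaged over diets, diet within each genotype and averaged over genotypes, and the interaction is the diet difference in the knockout minus that in the wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Data for 19938 genes were simulated with independent noise at each gene's residual spread over all 12 arrays, and some genes were changed together in the standard-diet knockout. The fit recovered 53.7% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 98.5% of 66 changed by 2. The simulated comparison gave 168 calls. With fewer changed genes the cutoff on p is stricter, so these shares overstate what a comparison with few changes would recover.

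Before the data were examined, 38 lists of genes of liver metabolism, stress, inflammation, other cell types and sex were fixed, together with the rule for named genes. Of these, 36 had at least 5 members and were tested with camera at a preset inter-gene correlation of 0.01 in 5 comparisons, 180 tests adjusted together. Each was also tested with an estimated correlation and with fry, and, as an addition after the data were seen, its median was ranked among 10000 random lists matched on expression in 20 bins. The named genes are Sirt3 and, per comparison, up to 10 called genes in each direction whose groups do not overlap, by size. Where fewer than 5 pass, the 5 with the smallest p in that direction are given as values. For the interaction the 10 with the smallest p are given, and for each list up to 4 called members, or otherwise 2 as values. Predicted, clone-named, olfactory, vomeronasal and small RNA genes were left out by name.

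The alternatives were other empirical Bayes settings, array weights, a fit of 2 groups only, the replicate number as a block, a filter on dim genes, all probe sets, quantile normalization and median centring, other thresholds, and leaving out each array. Added after the data were seen were the omission of 2 acute-phase arrays (knockout standard-diet replicate 1 and wild-type high-fat replicate 3), the omission of 2 knockout standard-diet arrays, cyclic loess, and a variance for the offset between the runs. That variance, with an SD of 0.215, was estimated from the covariance of both diet comparisons over 1228 olfactory, vomeronasal and taste receptor genes, called chemosensory below, which are dim (median level 4.23 against 6.70 for all genes). Figures were drawn with matplotlib 3.10.9.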

Results

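Expression of 19938 genes was measured in liver from 12 mice, 3 in each group of genotype and diet. The mice were wild type or lacked SIRT3 and ate a standard or a high-fat diet. The series was made to find how diet changes liver expression in these genotypes. Differences are given on the log2 scale with the SE of the fit. The median SE over genes was 0.114 within a diet or a genotype and 0.161 for the interaction.

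The signal of Sirt3, the targeted gene, was close to wild type on the standard diet and lower on the high-fat diet. Its group means were 9.04 (SD 0.0829, n = 3) in the wild type and 8.90 (SD 0.0681, n = 3) in the knockout on the standard diet. On the high-fat diet they were 9.18 (SD 0.0882, n = 3) and 8.76 (SD 0.234, n = 3). The differences were -0.14 (SE 0.108, limma adjusted p = 0.66) and -0.42 (SE 0.108, limma adjusted p = 1), so Sirt3 passed the test on neither diet. Every knockout array lay below every wild-type array on the same diet. The deposited files do not say where the probes lie relative to the targeted part, so this signal cannot check the genotype labels.

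**Figure D1:**
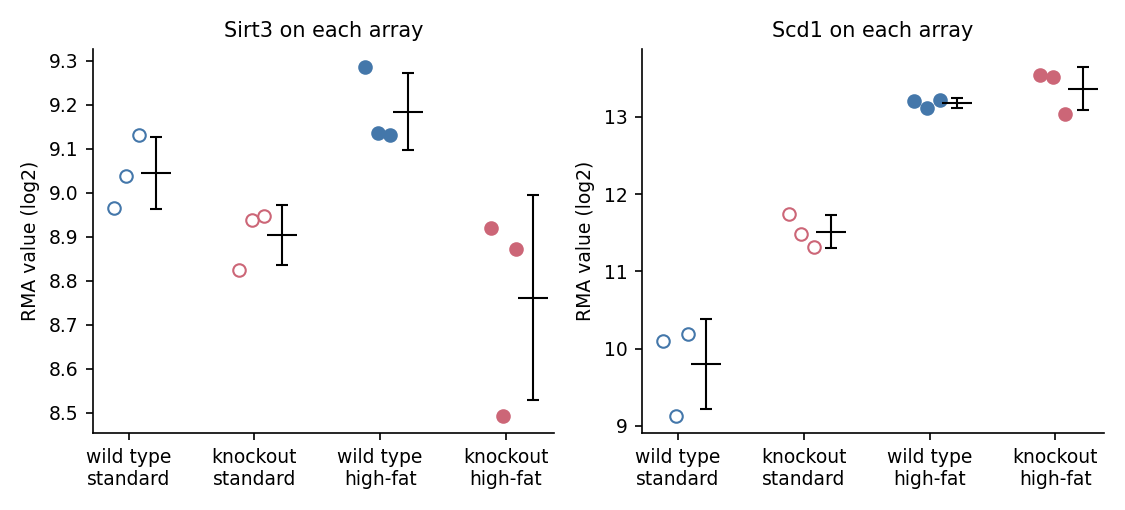
Sirt3 (left) and Scd1 (right) on each of the 12 arrays, as RMA values on the log2 scale by genotype and diet. Points are arrays, bars are group means with 1 SD, and Scd1 has means of 9.80 in the wild type and 11.5 in the knockout on the standard diet and of 13.2 and 13.4 on the high-fat diet.

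On the standard diet, Scd1, the desaturase that makes monounsaturated fatty acids, rose in the knockout. It was 3.27-fold higher (1.71, SE 0.217, limma adjusted p = 0.0261), with all 3 knockout arrays above all 3 wild-type arrays. It was the only called gene of 19938. At an unadjusted p under 0.05 stood 1939 genes, 1419 higher and 520 lower, and dim genes lay higher as a class on this diet. Groups did not overlap for 14.4% of genes against 10% by chance, and the part of that shift in this excess was not tested. The call did not hold without knockout standard-diet replicate 1 (adjusted p = 0.177) or 2 (0.16), although the difference stayed at 1.60 and 1.72. It also ended without high-fat wild-type replicate 1 (0.0664), 2 (0.0531) or 3 (0.0658), or without high-fat knockout replicate 1 (0.0585) or 2 (0.0531), which enter only the variance. Among other settings it ended with robust moderation (0.234), all probe sets (0.633) and a fit of the compared groups only (0.447). Other genes did not pass. Among those with the smallest p, the values were higher for Inmt (0.67, SE 0.131) and Crip2 (0.67, SE 0.125), and for Nsg2 (0.57) and Tuba3b (1.01). They were lower for Slco1a1, a hepatic anion transporter (-1.10, SE 0.237), for Cidec, a lipid droplet protein (-0.82, SE 0.187), and for Nudt7 (-0.86), Tuft1 (-0.82) and Zdhhc13 (-0.61). In that ranking 3 genes in each direction were left out by name.

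Of the gene lists, 11 were called on the standard diet with the preset correlation, and none of the 11 held with an estimated one, each at adjusted p = 0.804 with an estimated correlation. Male-biased liver genes lay lower in the knockout (median -0.46 over 21 members, camera adjusted p = 2.96e-07). Of these 0 were called over all genes with limma, and 4 fell when adjusted over the list alone. The list mean on knockout replicate 1 was -1.06, against -0.11 and -0.20 on replicates 2 and 3. Without replicate 1 the list median was -0.08 (adjusted p = 0.00487). The labels do not give the sex of the mice. On replicate 1 the female-biased list mean was 0.82 and that of the joint list of Y-linked and X-inactivation genes (6 measured members) -0.58. Lists of mitochondrial energy production were lower by small amounts: oxidative phosphorylation had a median of -0.04 over 68 members (adjusted p = 3.27e-05), with Cycs at -0.31 (its other probe sets at -0.31 and, on the dimmest, 0.35), and the TCA cycle -0.06 over 20 (adjusted p = 0.00485, percentile 22.96 of random lists matched on expression; median -0.03 without knockout replicate 1). In neither list was any member called over all genes or adjusted over the list alone. Among random lists matched on expression the oxidative phosphorylation median stood at the percentile 38.1, and without knockout replicate 1 it was 0.006068, no longer below 0 (adjusted p = 0.0442). Mitochondrial fatty acid oxidation (-0.02, percentile 64.2, adjusted p = 0.0207) and mitochondrial chaperones and proteases (-0.08, percentile 9.66, adjusted p = 0.0291) were called lower as well. Each of these lost its call without knockout replicate 1 (0.14 and 0.109), replicate 2 (0.139 and 0.142) or wild-type replicate 3 (0.141 and 0.102). Without knockout replicate 1 their medians were -0.005892 and -0.05814.

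Bile acid and sterol disposal genes were called lower (median -0.07 over 21, percentile 13.4, adjusted p = 0.0017), with Slco1a1 and the oxysterol hydroxylase Cyp7b1 (-1.12) having the smallest p, and 2 members fell when adjusted over the list alone. That call ended without knockout replicate 2 (0.059), and Cyp7b1 stood at -0.74 without replicate 1. Acute phase and cytokine response genes lay higher (median 0.23 over 33, adjusted p = 0.00287), and this rested on knockout replicate 1, whose list mean was 1.03 against 0.03 and 0.07 on the other arrays of the group. Without it the adjusted p was 0.647. Immediate early and heat shock genes such as Fos (0.69) and Gadd45b (0.71) were called higher (median 0.19, camera adjusted p = 0.0202). Without knockout replicate 1 the median was 0.09 and the adjusted p 0.197, and without wild-type replicate 1 the adjusted p was 0.103. Fos stood at 0.31 without knockout replicate 1, and Gadd45b at 0.34 without wild-type replicate 2. Markers of other cell types were called higher. They comprised bile duct cells (median 0.20 over 9, adjusted p = 0.00558, all 9 higher), pancreas, fat and muscle (0.16 over 23, adjusted p = 0.0145), and lymphocytes and NK cells (0.14 over 19, adjusted p = 0.0356). Dim genes lay higher as a class on this diet, and random lists matched on expression had medians of 0.09, 0.08 and 0.08, which places these lists at the percentiles 97.9, 98.8 and 94.8. Without knockout replicate 1 their adjusted p was 0.0759, 0.0649 and 0.156, and without wild-type replicate 3 it was 0.0598, 0.0991 and 0.137. Without knockout replicate 2 the pancreas, fat and muscle list stood at 0.138, with a list mean of 0.46 on that array, and the lymphocyte list at 0.0681. The bile duct genes Cldn7 (0.42) and Epcam (0.37) had the smallest p, and 2 of the 9 rose when adjusted over the list alone. Genes beside Sirt3 on its chromosome were not called (median 0.10, adjusted p = 0.42).

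**Figure D2:**
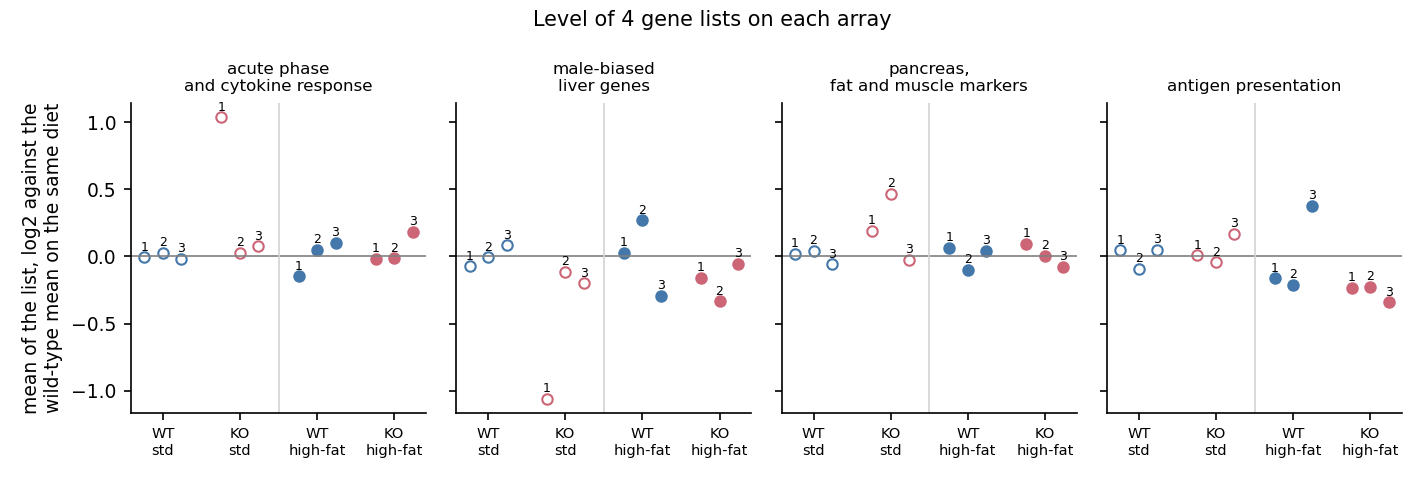
Mean level of 4 gene lists on each of the 12 arrays, as log2 differences from the wild-type mean on the same diet (open symbols standard, filled high-fat, numbers replicates). Knockout standard-diet replicate 1 stands at 1.03 for acute phase genes and -1.06 for male-biased genes, and high-fat wild-type replicate 3 at 0.38 for antigen presentation.

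On the high-fat diet no single gene passed the test between the genotypes: limma called 0 of 19938 genes, with 571 at an unadjusted p under 0.05, and 6.69% of genes had groups that do not overlap against 10% by chance. The values with the smallest p were higher in the knockout for Aldh1b1, a mitochondrial aldehyde dehydrogenase (0.46, SE 0.097), for Gadd45a (0.51) and Ces1d (0.38), and for Svs6 (0.47) and Ngef (0.48). They were lower for Slc25a22, a mitochondrial glutamate carrier (-0.45, SE 0.0919), for Gatm, the first enzyme of creatine synthesis (-0.34), and for Zfp820 (-0.51), Adamdec1 (-0.41) and Sirt3. Each of these had an adjusted p of 1.

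Among lists, 12 were called on this diet with the preset correlation and none held with an estimated one (adjusted p = 0.804 with an estimated correlation, and 0.898 for oxidative phosphorylation). Endoplasmic reticulum stress genes lay lower in the knockout (median -0.17, 18 of 23 members lower, adjusted p = 4.88e-05), with values of -0.41 for the foldase Pdia6 and -1.48 (SE 0.45) for Asns, whose groups overlap and which stood at -0.96 without wild-type replicate 2 and -2.12 without wild-type replicate 3. Circadian clock genes lay higher (median 0.17 over 19, adjusted p = 5.26e-05), with Wee1 at 0.90, and at 1.38 without knockout replicate 1. The clock list means were -0.14, 0.51 and 0.46 on the knockout arrays against -0.13, -0.02 and 0.15 on the wild-type arrays, so replicate 1 does not share the shift. These lists kept their calls without any single array. Xenobiotic metabolism genes lay higher (0.09 over 33, adjusted p = 6.2e-05), with Gstt3 at 0.44, and lost the call without knockout replicate 2 (0.106), where Gstt3 stood at 0.23. None of these lists had a called member over all genes or adjusted over the list alone.

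Genes of antigen presentation (median -0.23, all 13 lower, adjusted p = 6.2e-05), stellate cells and fibrosis (-0.11 over 23, adjusted p = 0.000222), macrophages and Kupffer cells (-0.13 over 21, adjusted p = 0.00153) and the interferon response (-0.11 over 21, adjusted p = 0.0356) were called lower in the high-fat knockout. Lum stood at -0.50, and H2-Ab1 and Cd68 at -0.62 and -0.32, or at -0.33 and -0.16 without wild-type replicate 3. High-fat wild-type replicate 3 lay above the other arrays of its group for antigen presentation (0.38) and macrophage genes (0.30). Without it the adjusted p of these lists was 0.586, 0.111, 0.551 and 0.555, and the macrophage and interferon lists turned to the other direction. The interferon call also ended without knockout replicate 1 (0.16) or 3 (0.242). The remaining calls were endothelial markers lower (-0.06, adjusted p = 0.0473, percentile 13.8 of random lists matched on expression), and lipoprotein assembly (0.04, 0.0169), acute phase (0.04, 0.019), female-biased (0.11, 0.0311) and oxidative phosphorylation genes (0.02, 0.0401) higher. Each ended without several single arrays, with the largest adjusted p at 0.424 (without knockout replicate 1), 0.213 (knockout 3), 0.27 (wild type 1), 0.356 (knockout 2) and 0.936 (knockout 3) in that order. Averaged over both diets, genotype gave 0 calls in limma, with 1323 genes at an unadjusted p under 0.05.

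Genes that differed most between the diets in the wild type include Scd1, the lipid uptake genes Lpl and Cd36, the clock output gene Dbp and several genes of sterol synthesis. The rises were largest for Scd1 (10.4-fold, 3.38, SE 0.217), for the lipoprotein lipase Lpl (3.95-fold, 1.98, SE 0.203), for the methyltransferase Inmt (3.77-fold), for Cyp2c70 (3.63-fold) and for the fatty acid transporter Cd36 (3.54-fold, 1.82, SE 0.191). Rises followed in Themis, Dbp, Adam11, Zfp991 and Ddah1, between 2.73- and 3.52-fold. Falls were largest for the steroid hydroxylase Cyp17a1 (6.55-fold lower, -2.71, SE 0.356), for squalene epoxidase, Sqle (4.06-fold lower, -2.02, SE 0.289), for Idi1, Msmo1 and Cyp51 of sterol synthesis, for the oxysterol hydroxylase Cyp39a1, and for Fdps, Cyp2b10, Tm7sf2 and Slco1a4, the last 2.25-fold lower. Limma called 1194 genes (858 up, 336 down), of which 44 changed at least 2-fold, and 30.3% of genes had groups that do not overlap against 10% by chance. Among the largest falls 2 genes were left out by name.

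Many of these genes differed between the diets in the knockout too, again across the normalization runs. Scd1 rose 3.61-fold (1.85, SE 0.217), Cd36 3.89-fold, Lpl 3.05-fold, and the estrogen sulfotransferase Sult1e1 4.03-fold (2.01, SE 0.404; 2.62 without high-fat knockout replicate 1). Themis, Dbp, Wee1, Hsd3b3, Zfp991 and Bcl6 rose between 3.04- and 3.57-fold. Cyp17a1 fell 6.89-fold (-2.79, SE 0.356) and Sqle 4.33-fold, followed by Msmo1, Fdps, Cyp51, Cyp39a1, Tubb2a and Tm7sf2, by Pdk4, the kinase that restrains pyruvate oxidation (-1.58, SE 0.335), and by Igfbp1, a liver gene lowered by insulin (-1.51, SE 0.375). Limma called 1018 genes (488 up, 530 down), 62 of them at least 2-fold, and 23.8% of genes had groups that do not overlap against 10% by chance. Averaged over genotypes the diet gave 3582 calls (2049 up, 1533 down). Both genotypes called 274 genes up, where 21 would be shared by independent lists, and 175 down, where 8.93 would be. Those expected numbers leave out the offset between the runs, which both comparisons share. Chemosensory genes, with little expected role in liver, shared 26 calls up and 22 down against 2.77 and 1.79, so the excess does not show a shared effect of diet. None was called in opposite directions, and 97.0% of genes called in either had the same sign. Across the 19938 genes, which are not independent replicates, the diet differences of the genotypes had a Pearson r of 0.67 and a Spearman rho of 0.61.

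Every diet comparison lies across the separate normalization runs, and small differences cannot be read as effects of diet. Chemosensory genes gave a call in 11.3% of 1228 cases in the wild type (other genes 5.64%) and 7.66% in the knockout (other genes 4.94%), and their diet differences had an r of 0.70 between genotypes. With a variance for this offset added, 7 calls were left in the wild type (Scd1, Inmt, Adam11, Lpl, Cd36, Themis and Cyp17a1), 5 in the knockout (Adam11, Cd36, Cyp17a1, Fdps and Themis) and 9 averaged over genotypes. The SD of 0.215 behind it came from dim genes and was given to every gene. Over all genes the same covariance gave an SD of 0.19, with any shared effect of diet included. A simulated offset of SD 0.2 without a diet effect gave 3116 wild-type calls, against 1194 observed. The added variance may thus be too large for many genes, and these counts do not show that the lost calls come from the runs. After median centring the wild-type split became 425 up and 618 down, and the averaged split 1510 up and 1988 down, so in these comparisons the balance of rises and falls rests on the scaling. In the knockout it changed little, with 500 up and 519 down against 488 and 530 in the main fit.

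Cholesterol synthesis was the list that differed most between the diets. In the wild type 13 of 21 members fell (15 adjusted over the list alone), the median was -0.67 and the camera adjusted p was 2.52e-18. In the knockout 16 fell (19 adjusted over the list alone), with a median of -0.77 and an adjusted p of 5.83e-18. With an estimated correlation both calls were lost (adjusted p = 0.804), and fry gave adjusted p of 0.0458 and 0.0293. Among the members, Fdps stood at -1.56 and -1.77, Tm7sf2 at -1.20 and -1.49, and Dhcr7 at -0.95 and -1.06. Srebf2, the transcription factor of this pathway, stood at -0.54 and -0.65. The calls held without any single array, across the runs as for all diet results.

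**Figure D3:**
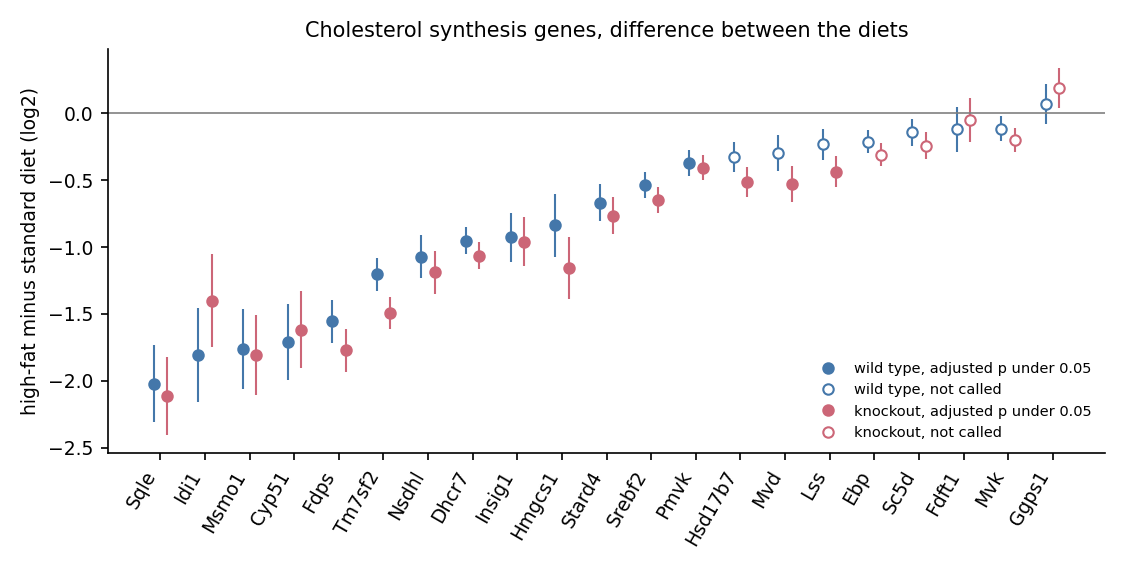
Difference between the high-fat and the standard diet (log2) for the 21 measured cholesterol synthesis genes, in the wild type (blue) and the knockout (red). Bars are 1 SE of the fit with 3 arrays per group, and filled points have a limma adjusted p under 0.05 (13 in the wild type, 16 in the knockout).

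Circadian clock genes differed between the diets in both genotypes. In the wild type 6 of 19 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.00874), and in the knockout 8 rose and 1 fell (also 8 and 1 over the list alone, median 0.66, adjusted p = 0.000307). Dbp and Bhlhe41, an output gene and a repressor of the clock, rose in both, Bhlhe41 by 1.33 (SE 0.11) and 1.27 (SE 0.11), while the activator Arntl stood at -1.04 (SE 0.2) and -1.22 (SE 0.2). Both list calls were lost with an estimated correlation (adjusted p = 0.804), and the labels give no time of killing. The lipid droplet and lipid uptake list was called higher in the knockout (median 0.09, 6 of 23 up and 1 down, and 9 and 2 adjusted over the list alone, adjusted p = 0.00558; with an estimated correlation adjusted p = 0.804), with Fabp4 at 0.94 and Fitm1 at 1.21. In the wild type 7 rose and 2 fell (8 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.132). Of 28 genes of fatty acid and triglyceride synthesis, 4 rose and 2 fell in the wild type (5 and 5 adjusted over the list alone) and 4 rose and 3 fell in the knockout (6 and 4). Srebf1 rose by 1.27 and 1.18 and the desaturase Fads1 fell by 0.89 and 0.70, and the list was called in neither (adjusted p = 0.563 and 0.72).

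Oxidative phosphorylation genes were called lower on the high-fat diet in the wild type (median -0.21, 62 of 68 lower, 4 fell, 13 adjusted over the list alone, adjusted p = 2.47e-13; with an estimated correlation adjusted p = 0.804), among them Uqcr10 at -0.46 and Ndufb10 at -0.42. In the knockout the median was -0.10, with 0 members called (adjusted p = 0.008; 0.898 with an estimated correlation), and the call ended without high-fat knockout replicate 1 (0.241) or standard-diet knockout replicate 3 (0.129). Endoplasmic reticulum stress genes were called lower in the knockout, where 10 of 23 fell (14 adjusted over the list alone, median -0.38, adjusted p = 1.01e-06; with an estimated correlation adjusted p = 0.804). They included the chaperone Hspa5 (-0.67), Hyou1 (-0.76), Manf (-0.73) and Sdf2l1 (-1.19). In the wild type 1 member, Vldlr, rose by 0.61 and the median was -0.16 (adjusted p = 0.0249), a call that was lost with an estimated correlation (adjusted p = 0.804) and ended without high-fat replicate 1 (0.0968) or 3 (0.0887) or standard-diet replicate 3 (0.222).

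Other lists were called in 1 genotype, and an estimated correlation ended each of these calls (adjusted p = 0.804, or 0.885 for the urea cycle list). In the wild type, antigen presentation genes were called higher (4 of 13 rose, 5 adjusted over the list alone, median 0.42, adjusted p = 0.00615), as were lymphocyte and NK cell markers (5 of 19, and 7 over the list alone, 0.23, adjusted p = 0.00558) and interferon response genes (2 of 21, and 5 over the list alone, 0.16, adjusted p = 0.0138). H2-Ab1 rose by 1.10, Ncr1 by 0.90 and Ifit3 by 0.65. Without high-fat wild-type replicate 3 these lists had adjusted p of 0.166, 0.0937 and 0.281, and the interferon list also lost its call without standard-diet wild-type replicate 1 (0.061). Gluconeogenesis (1 of 17 fell, -0.21, adjusted p = 0.0207), urea cycle (4 of 31, and 5 over the list alone, -0.05, percentile 46.8, adjusted p = 0.0207), TCA cycle (1 of 20, and 0 over the list alone, -0.09, percentile 12.8, adjusted p = 0.00872) and mitochondrial fatty acid oxidation genes (-0.08, percentile 24.4, adjusted p = 0.0125) were called lower, with Got1 at -0.61, Arg1 at -0.72, Asl at -0.60 and Mdh2 at -0.31. Without standard-diet wild-type replicate 3 the first, second and last stood at 0.0606, 0.0922 and 0.0606, and without high-fat wild-type replicate 2 gluconeogenesis stood at 0.0633. In the knockout, male-biased genes were called higher (2 of 21 rose, 4 over the list alone, median 0.42, adjusted p = 0.00247), as were xenobiotic metabolism genes (5 rose and 1 fell of 33, and 9 and 4 over the list alone, 0.17, adjusted p = 0.00872). Immediate early genes were called lower (1 rose and 1 fell of 26, and 1 and 2 over the list alone, -0.22, adjusted p = 0.0345), with Gadd45b at -1.30. The male-biased and immediate early calls ended without standard-diet knockout replicate 1 (0.15 and 0.387), and the xenobiotic and immediate early calls without high-fat knockout replicate 2 (0.128 and 0.0934). The immediate early call also ended without high-fat knockout replicate 3 (0.141) or high-fat wild-type replicate 3 (0.0543).

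The interaction asks whether the genotypes respond to the diet by different amounts. Scd1 rose less in the knockout (1.85) than in the wild type (3.38), a difference of -1.52 (SE 0.307) with an unadjusted limma p of 0.000187 and an adjusted p of 0.945. Its means were close on the high-fat diet (13.2 in the wild type, 13.4 in the knockout) and apart on the standard diet (9.80 and 11.5). The interaction value of Scd1 thus largely repeats its standard-diet difference. Limma called 0 of 19938 genes, with 944 at an unadjusted p under 0.05, of which 131 were positive and 813 negative. The median over all genes was -0.05, and a negative sign was thus shared by most genes with a small p. The other values with the smallest p were negative as well: Marcksl1 (-0.59), Gsdmc2 (-0.71), Krtap4-6 (-0.68), Slc25a22 (-0.54), Swsap1 (-0.65), Hspb3 (-0.60), Il23a (-0.68), the endoplasmic reticulum cochaperone Sdf2l1 (-0.92, SE 0.226) and Crip2 (-0.72). In that ranking 4 genes were left out by name.

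With the preset correlation 13 lists were called for the interaction, and none held with an estimated one (adjusted p = 0.804 for each). The response of endoplasmic reticulum stress genes was more negative in the knockout (median -0.32, 19 of 23, adjusted p = 0.000222, 1 member when adjusted over the list alone). That of oxidative phosphorylation genes was more positive (median 0.09, 57 of 68, adjusted p = 2.96e-07). These lists kept their calls without any single array, and the full set stands in the closing section.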

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

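The tests of separate normalization runs, of the array with an acute-phase response, of food, of the acute-phase response and of 1 unusual array for Scd1, and the ranks among random lists were chosen after the result was seen, while the counts of other splits and the omission of each array were planned.

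The response to diet differed between the genotypes, by the interaction test, in 13 gene lists at the preset correlation, none of them with an estimated one (adjusted p = 0.804). More positive in the knockout were oxidative phosphorylation (adjusted p = 2.96e-07), xenobiotic metabolism (0.000489), male-biased genes (0.00069), mitochondrial fatty acid oxidation (0.00872), bile acid and sterol disposal (0.0145) and the TCA cycle (0.0145). More negative were endoplasmic reticulum stress (0.000222), and macrophage (0.00186), antigen presentation (0.00874), lymphocyte (0.0123), bile duct (0.0202), stellate cell (0.0257) and neutrophil genes (0.0356). Among random lists matched on expression, the medians of mitochondrial fatty acid oxidation and the TCA cycle stood at the percentiles 70.7 and 71.3, bile acid disposal at 91.1, and lymphocyte, bile duct and neutrophil genes at 6.62, 5.12 and 3.22, so part of these shifts is shared by other genes of their level. Leaving out 1 array ended 11 of the 13 calls, and the largest adjusted p of each was as follows. Without high-fat wild-type replicate 3 it was 0.586 for macrophage, 0.476 for antigen presentation, 0.285 for lymphocyte, 0.275 for bile acid and 0.207 for stellate cell genes. Without standard-diet knockout replicate 1 it was 0.408 for male-biased, 0.289 for neutrophil and 0.191 for bile duct genes, without high-fat knockout replicate 3 it was 0.202 for the TCA cycle and 0.101 for mitochondrial fatty acid oxidation, and without high-fat knockout replicate 2 it was 0.0574 for xenobiotic metabolism.

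Some named genes differed in opposite directions, with no overlap between the arrays of the compared groups. Between genotypes, the knockout differed on the standard diet by 0.36 in Gsdmc2, 0.40 in Hspb3 and 0.27 in Marcksl1, against -0.34, -0.20 and -0.32 on the high-fat diet. Between diets, the wild type differed by 0.42 in Hspb3 and 0.48 in Marcksl1, and the knockout the other way. These opposite directions were not tested beyond the interaction fit (limma adjusted p = 0.945 for each), and the genes were named because of their small interaction p.

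In a fit of all probe sets, 1677 of 15284 (11.0%) outside the fitted genes were called for diet averaged over genotypes, a comparison across the normalization runs. In the main fit the share was 17.97% of all genes and 23.05% of chemosensory genes, so 11.0% does not stand above the share that the run offset can give. For genotype, limma called 0 of these probe sets on either diet.

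Other groupings of the arrays were counted to see whether chance can be excluded. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. On the standard diet the real genotype split called 1 gene and the highest other split 0, so 1 split called as many. The diet splits called 1194 genes in the wild type and 1018 in the knockout, against 1 and 3 in the highest other, so 1 split called as many in each. For diet averaged over genotypes, 1 of 100 splits called as many as the real 3582, with 7 in the highest other, and a split of the arrays by chance is thereby excluded at 0.05, although not an offset between the runs. Where the real count is 0, every split reaches it, so the count decides nothing: this holds for genotype on the high-fat diet (10 of 10 splits, highest other 5), genotype averaged over diets (100 of 100, highest other 21) and the interaction (100 of 100, highest other 218). The split with 218 calls labelled as knockout standard-diet wild-type 1 and 3 and knockout 3, and high-fat wild-type 3 and knockout 1 and 2. Standard-diet groups enter the interaction with the opposite sign. High-fat wild-type 3 and knockout 1 and 2 thus stood on the side of standard-diet wild-type 2 and knockout 1 and 2. A count that high points to some structure of the samples, which was not tested, and this split was picked as the highest of 100, of which 3 called any gene.

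Diet calls and the separate normalization runs. An offset from the runs, which both genotypes share, may account for many small diet calls, since chemosensory genes were called in 11.3% of cases in the wild type, more often than other genes. At a size of at least 2-fold, limma called 44 genes in the wild type and 62 in the knockout. Of the chemosensory genes 2 and 0 passed, where 2.76 and 4.07 would pass at the share of other genes. These are too few and too dim to decide, so for these calls as a set diet and run cannot be told apart. The largest lie beyond every chemosensory gene: Scd1 at 3.38 in the wild type and Cyp17a1 at -2.71 and -2.79, against 1.27 and 0.904, and with the run offset added the adjusted p was 0.00037 for Scd1 in the wild type, 0.0636 in the knockout, and 0.0435 and 0.0466 for Cyp17a1. For cholesterol synthesis the values argue against a run offset that is independent from gene to gene as the whole source. The lowest median among random lists was -0.33 for chemosensory genes and -0.18 for other genes of the same level, against -0.67 and -0.77. This list was taken up because it differed most, and the random lists hold unrelated genes. An offset shared by the members of the list was not tested. An effect of diet, or of another difference between the diet groups such as the time of killing, which the labels do not give, stays open there as a hypothesis.

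Gene lists in the knockout on the standard diet and 1 array with an acute-phase response. Knockout replicate 1 holds acute phase genes far above the other arrays, and without it 4 of the 11 called lists stayed called (adjusted p = 0.00487 for male-biased genes, 0.00117 for bile acid disposal, 0.0304 for the TCA cycle with a median of -0.03, and 0.0442 for oxidative phosphorylation, whose median of 0.006068 was then no longer lower), which leaves the set undecided. For male-biased genes the median went from -0.46 to -0.08184, so this array could be the source of most of that shift. A mixed sample was not tested and stays open, since the labels do not give sex: Eif2s3y and Uty lay low on this array, while Xist, made by the inactive X of females, had a mean of 4.52 (SD 0.0842) in the group against 4.46 in the wild type, and no array known to be female shows that its probes respond. A genotype effect stays open as a hypothesis for the male-biased, TCA cycle and bile acid lists, although all 3 calls are lost with an estimated correlation (adjusted p = 0.804) and the bile acid call without knockout replicate 2 (0.059). Slco1a1 and Cyp7b1, the bile acid genes with the smallest p, also belong to the male-biased list, so these lists are not independent.

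Higher Scd1 in the knockout on the standard diet. The difference does not rest on 1 array, since the lowest with 1 array left out was 1.37. Nor does it rest on the array with the acute-phase response. The lower of both other knockout arrays lay 1.13 above the highest wild-type array, with a wild-type SD of 0.584. Both checks were set after Scd1 had been picked for its difference, so they do not test whether that difference arose by chance. Without knockout replicate 1 the call ended (limma adjusted p = 0.177). Food eaten before killing was not measured and stays open, although all mice were fasted for 24 h per the labels. As a set the other fatty acid synthesis genes did not rise with Scd1, since 12 of the 27 lay higher. The food test was changed after its outcome was known. It was first judged on the median of these genes (-0.06, SD 0.291), which counted against food, and was replaced by the count because members that go both ways leave such a median undecided. An effect of genotype stays open as a hypothesis, on a call that several alternatives end.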

How the results depend on the processing

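Omission of 2 arrays, cyclic loess and the run offset were chosen after seeing the data; the other alternatives were planned. Sirt3 stayed lower in the knockout in all settings run, between -0.22 and -0.08 on the standard diet and between -0.61 and -0.29 on the high-fat diet, with adjusted p of at least 0.483 and 0.0766. In the comparisons below the cause was not tested unless the setting itself gives it.

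Genotype, standard diet (1 gene, Scd1): the count was 0 with robust moderation, all probe sets, 2 groups only, the strict threshold of 0.01, and without 2 acute-phase arrays or 2 knockout standard-diet arrays. It was 80 with unadjusted p and a fold of 1.5, and 0 to 6 without 1 array. Scd1 had a difference between 1.37 and 1.90 and an adjusted p between 0.00571 and 0.912. Genotype, high-fat diet (0): 1 without 2 acute-phase arrays (Insig2), 17 with unadjusted p and fold, and 0 to 1 without 1 array. Genotype averaged (0): 1 without 2 knockout arrays (Angptl8), 19 with unadjusted p and fold, and 0 to 2 without 1 array. Interaction (0): 89 with unadjusted p and fold, and 0 to 1 without 1 array.

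Diet, wild type (1194): 3632 with array weights, 346 among genes above the median level, 362 with unadjusted p and fold, 2214 and 274 at the thresholds of 0.1 and 0.01, 7 with the run offset, and 389 to 1322 without 1 array. It was 389 and 733 without high-fat wild-type replicate 1 and 2, and 508, 447 and 435 without standard-diet wild-type replicate 1, 2 and 3. Diet, knockout (1018): 2015 with array weights, 431 above the median level, 1532 after quantile normalization, 625 without 2 acute-phase arrays, 43 without 2 knockout standard-diet arrays, 381 with 2 groups only, 409 with unadjusted p and fold, 1926 and 232 at 0.1 and 0.01, 5 with the run offset, and 360 to 1286 without 1 array. It was 508 and 528 without standard-diet knockout replicate 1 and 2, and 360 and 542 without high-fat knockout replicate 2 and 3. Diet averaged (3582): 1628 above the median level, 2326 without 2 knockout arrays, 297 with unadjusted p and fold, 1519 at 0.01, 9 with the run offset, and 2644 to 3519 without 1 array.

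Of 55 called list tests, 0 held with an estimated correlation and 2 with fry. The number called was 33 without 2 acute-phase arrays and 36 to 68 without 1 array, with 36 without high-fat wild-type replicate 3. Without 2 knockout standard-diet arrays, which leaves 1 array assumed to vary like the other groups, these values turned over: on the standard diet Decr1 0.05, Hadhb 0.0201, Ndufa6 0.0001297 and Yme1l1 0.01566, and for the interaction Decr1 -0.05759 and Slco1b2 -0.14. The lists that turned over had adjusted p of 0.511 (mitochondrial fatty acid oxidation), 0.719 (mitochondrial chaperones) and 0.505 (pancreas, fat and muscle) on the standard diet, and 0.968 (mitochondrial fatty acid oxidation) and 0.975 (neutrophil) for the interaction. On the high-fat diet the interferon list turned over without wild-type replicate 3 (0.555) and without 2 acute-phase arrays (0.62), as did macrophage genes (0.551 and 0.642). Their lowest values were 0.000325 without wild-type replicate 2 (interferon) and 1.57e-07 without wild-type replicate 1 (macrophage). The male-biased interaction list turned over without 2 acute-phase arrays (0.49).

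With the replicate number as a block, the counts were 1, 0, 1158, 1025, 0, 3601 and 0 in the order genotype on each diet, diet in each genotype, genotype averaged, diet averaged and interaction, and 57 list tests were called, 55 of them shared. Whether the numbers pair the arrays stays open. Of 12 same-numbered pairs, 4 correlated above 0.1 (range -0.21 to 0.41), and 7 of 12 arrays had their best match in another group under their own number. The counts to be had by chance were not computed. Weak signals near background limit what small differences in dim genes can show.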

Other observations

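The genes below that are not in the fixed lists, and the grouping of the clock genes, were chosen after their values were seen, and no explanation is offered.

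Single genes of glycolysis and sterol transport also differed between the diets, across the normalization runs, while their lists were not called. In the wild type 4 of 17 glycolysis and glycogen genes fell, Aldoa by 0.54, Tpi1 by 0.42, Ldha by 0.30 and Pgk1 by 0.30, and in the knockout 3 fell, with Aldoa at -0.55. The glycolysis list was called in neither, with a median of 0.07 and 0.05 (camera adjusted p = 0.514 and 0.668). The sterol exporters Abcg5 and Abcg8 and the cholesterol transporter Abca1 rose by 0.92, 0.58 and 0.57 in the wild type and by 1.00, 0.78 and 0.64 in the knockout. With 21 members measured, the list of bile acid and sterol disposal was not called (adjusted p = 0.983 and 0.0765).

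Single arrays stood apart from their groups. On knockout standard-diet replicate 1 the acute phase genes Saa1, Saa2 and Lcn2 lay at 11.8, 13.3 and 12.7, against at most 5.25, 7.47 and 8.37 on the other arrays of the group. Sult3a1, a female-biased sulfotransferase, lay at 8.64 there and at 3.30 and 3.03 on the others, the female-biased list mean was 0.82, and the Y-linked genes Eif2s3y and Uty lay at 7.55 and 6.51, against standard-diet wild-type values of 8.88 to 9.05 and 7.86 to 8.11. They lay at 8.19 and 7.43 on replicate 2. On knockout standard-diet replicate 2 the muscle genes Acta1 and Ckm lay at 9.80 and 8.97, against at most 7.49 and 7.67 on the other 11 arrays. On the high-fat diet, wild-type replicate 3 had Saa1 at 7.05, Saa2 at 9.72 and Lcn2 at 9.38, and knockout replicate 3 had them at 7.88, 9.10 and 8.46, with acute phase list means of 0.10 and 0.18. The omission of 2 acute-phase arrays kept knockout replicate 3.

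Clock genes varied among high-fat mice. Arntl, Clock, Cry1 and Nfil3 were set against the other measured genes of the clock list, on values relative to all arrays. The mean of the other genes minus that of this set was -0.25, 0.35 and 0.93 on the high-fat wild-type replicates 1 to 3. It was 0.22, 1.19 and 1.08 on the high-fat knockout replicates, against -1.05 to -0.02 on the standard diet. The split of the high-fat arrays that called 5 genes set wild-type 1 and 2 and knockout 1 against the others. It called Thrsp (2.36), Rgs16 (2.26), Slc16a1 (-1.07), Cldn1 (-0.82) and Slc30a10 (-0.79), none of them called between genotypes (adjusted p = 1).

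Leaving out 1 array added calls in some comparisons. Without standard-diet knockout replicate 3, Sult2a8 (-1.22), Eif2s3y (-1.12), Fabp2 (-1.02), Lnpk (-0.84) and Gm24463 (-1.01) joined Scd1 on the standard diet, and Sult2a8 was called for the interaction (1.20). On the high-fat diet Insig2 (-0.60) was called without wild-type replicate 3 and Wee1 (1.38) without knockout replicate 1. Averaged over diets, Sult2a8 (-0.63) and Gm24463 (-0.69) were called without standard-diet knockout replicate 3, Ddah1 (0.67) was called without high-fat wild-type replicate 3 and Scd1 (0.78) without standard-diet wild-type replicate 2.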
